A study of Solanum lycopersicum with 24 samples.

How the data were processed

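Leaves of tomato (Solanum lycopersicum) cultivar Micro-Tom were profiled on Affymetrix Tomato Gene 1.1 ST arrays, with 24 arrays in 8 groups of 3. Per the labels, plants aged 30 days spent 2 h a day in an anechoic box on 3 days, with or without a tone of 1000 Hz at 90 dB. They were dipped in a suspension of Pseudomonas syringae pv. tomato (Pst), a bacterial pathogen of tomato that the labels call both DC3000 and DC300, or in a mock solution of surfactant and magnesium chloride. Leaves were harvested at day 1 or day 3, and each biological replicate combined 4 plants. The labels do not settle whether the days count from the sound or from the dip, so "day 1" and "day 3" stand for the labels' days only. Groups and replicate numbers were taken from the sample titles.

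The deposited values are log2 expression levels of 67795 probe sets, made with RMA per the submitters' processing notes. The version of RMA and the level at which probes were summarised are not given in the sources used here. Small negative values occur. Detection calls and scanner files were not used here, so signal over background is unknown. RMA makes the distributions of the arrays more alike, so a change shared by most genes would be at least partly hidden. The medians of the deposited arrays still ran from 1.07 to 1.17.

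Genes were named from the platform annotation, which can be old. Of the probe sets, 23194 had 1 gene symbol, 170 had several and 44431 had none. No gene was named from a probe set with several symbols. The 21326 genes comprised 20429 with a LOC number and 897 with another symbol. For the 914 genes with more than 1 probe set, the one with the highest mean over all arrays stood for the gene. Where more than 1 probe set of a gene passed the test, their signs were opposite for 0 of 11 genes for Pst at day 1 and 1 of 49 at day 3. Synonyms came from a RefSeq table of assembly SLM_r2.1, whose coordinates were not used here.

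All arrays were fitted in limma 3.58.1 (R 4.3.3) with a mean for each group, and 16 comparisons of group means were tested after the default empirical Bayes step. The fit had 16 residual and 5.63 prior degrees of freedom. Benjamini-Hochberg adjustment ran over all probe sets within each comparison, and an adjusted p under 0.05 was called. A further count asked for an absolute log2 fold change of at least 1 as well. Errors given after ± with log2 fold changes are standard errors of this fit, with n = 3 arrays per group. The fit takes 1 spread per probe set for all groups, and the groups did not vary alike. Control arrays of day 1 correlated with their own group at means of 0.963 to 0.969, those of day 3 at 0.982 to 0.984. Errors and p-values of comparisons that use day 1 groups can therefore be too small. An exact test of 3 arrays against 3 cannot give a p under 0.1. The number of arrays limits the precision.

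Gene lists for defence, hormones, stress, photosynthesis, metabolism, growth and other organs, the rule for naming genes and the alternatives were fixed before the data were examined. The annotation carries symbols only, so list members were chosen by symbol after the annotation was read and before any level was compared between groups. The lists of plastid genome, cytokinin, carotenoid, polyamine and GABA, and sucrose and sugar genes, 5 in all, were added at that point. Of 28 lists with 467 genes, 26 had at least 5 measured genes and were tested with camera at a preset correlation of 0.01, adjusted over the lists of a comparison. The circadian clock and vascular lists were too short to be tested. camera with an estimated correlation and fry were alternatives. A member counts as higher or lower where it passed over all probe sets, and counts "adjusted over the list alone" stand beside these.

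For the first 6 comparisons the rule for named genes took the 8 highest and 8 lowest changes among called genes whose arrays did not overlap between the groups, and for the others 4 and 4, with no demand on overlap for differences of comparisons and for the average. It added up to 2 called members on each side of each list, the 5 lowest p-values where fewer than 5 genes passed, and a fixed set of defence genes. PR1 was taken as PR1b1 and PR-1a1. JA3 (a synonym of MYC2) and NIM1 (of NPR1) stood for those genes, SRG1 (of SLJAZ3) for JAZ1 and PIIF for proteinase inhibitor II. These substitutions were made before the genes' values were seen, and EDS1, Pti5 and FLS2 were not analysed here. After the annotation was read, the 6 highest and 6 lowest genes with a symbol other than a LOC number were added. The list members aos, aoc, PR-P2, PSBP, MPK3, JA2 and loxC were named after their values were seen.

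Alternatives were the replicate number as a block, a fit of only the groups compared, a trended and robust prior, removal of dim probe sets, quantile normalization of the deposited values, array weights, only probe sets with 1 gene, and each array left out in turn. The dim filter left out probe sets whose mean was under the 30th percentile in all groups and kept 56585. Deviations of arrays from their group means were compared to see whether the replicate numbers pair the samples.

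The fit was tested on simulated data of 67795 probe sets with the fitted spread of the real ones and 200 changed. The changed ones were drawn from probe sets with a mean level over 3, and the noise was independent. Recovery of changes in dimmer probe sets was not tested. The simulated spread of a probe set was the same in all groups, while real controls varied more at day 1 than at day 3. The rates below may therefore not hold for real comparisons that use day 1 groups. For Pst against control at day 1, log2 changes of 0.5, 1 and 2 were recovered in 8.96%, 85.1% and 95.5% of the changed probe sets, with 2 false calls among 128. For the interaction of sound and Pst at day 1 the shares were 1.49%, 67.2% and 98.5%, with 7 false calls among 118. For sound averaged over 4 strata they were 86.6%, 98.5% and 100%, with 10 false calls among 200. Of 20 simulated lists, camera called the 1 that was shifted and 0 of the others. Members of these lists were drawn independently, so false calls that come from correlated genes could not show.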

Results

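Leaf transcript levels were measured in 8 groups of tomato plants that combined sound or silence, a dip in Pst or in mock solution, and harvest at day 1 or day 3, with 3 arrays in each group. Pairs of arrays correlated at 0.966 to 0.992 over all probe sets, and 0 pairs held identical values. The first principal component of the 15590 probe sets with a mean over 3 took 45.6% of the variance and the next 13.1%. On the first component the control arrays of day 1 lay at -13.2, 1.13 and -23.8, and those of day 3 at -40.2, -43.2 and -42.6.

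The first comparison asked how leaves responded to Pst at day 1. Genes of the jasmonate and wound response rose, among them threonine deaminase (Td), higher with Pst by a log2 fold change of 5.78 ± 0.50 (SE, n = 3 per group). The metallocarboxypeptidase inhibitor mcpi rose by 4.82 ± 0.46, the arginase ARG2 by 3.65 ± 0.40, the leucine aminopeptidase lap2 by 3.29 ± 0.34 and loxD, a lipoxygenase of jasmonate synthesis, by 2.22 ± 0.22. Of 24 jasmonate genes 13 rose and 0 fell, and 15 were higher and 2 lower adjusted over the list alone (camera adjusted p = 5.24e-10, and adjusted p = 0.0440 with an estimated correlation). Allene oxide synthase (aos) rose by 1.81 ± 0.31 and allene oxide cyclase (aoc) by 1.47 ± 0.19. The highest change of a named gene was that of ca3, which went from a level of 0.56 ± 0.15 (SD) in controls to 7.66 ± 0.32 with Pst. LOC101248628 rose by 5.93 ± 0.40 and LOC101248922 by 5.62 ± 0.37.

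Pathogenesis-related (PR) genes rose at day 1 as well, 5 of 11 over all probe sets and 6 adjusted over the list alone (camera adjusted p = 5.91e-05, but adjusted p = 0.133 with an estimated correlation). TSI-1 rose by 2.93 ± 0.38, P4, of the PR-1 type, by 2.94 ± 0.49, PR-P2 by 1.61 ± 0.22 and PR1b1 by 1.33 ± 0.23. These errors pool all groups, and controls varied more at day 1 than at day 3 in TSI-1, PR-P2 and PR1b1. Of 13 polyamine and GABA genes 4 rose, with 6 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.000730, but adjusted p = 0.133 with an estimated correlation). They included the arginine decarboxylase adc1 at 1.51 ± 0.17 and SPM1 at 1.13 ± 0.16. WRKY transcription factors rose in 2 of 5, and in 4 adjusted over the list alone (camera adjusted p = 0.000882, but adjusted p = 0.0873 with an estimated correlation), with WRKYIId-2 at 0.81 ± 0.14. The cytokinin oxidase SlCKX4 rose by 2.12 ± 0.17, and det2, a reductase of brassinosteroid synthesis, by 1.81 ± 0.27. Among the fixed defence genes SRG1 rose by 1.31 ± 0.19 and ACO1, of ethylene synthesis, from a level of 1.69 ± 0.21 (SD) to 2.77 ± 0.08 (limma adjusted p = 0.000294). JA3 rose by 0.56 ± 0.13, a call that ended without any 1 of the 6 arrays. NIM1 (0.14 ± 0.12), PIIF (0.10 ± 0.16) and PR-1a1 (0.03 ± 0.12) did not pass.

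Photosynthesis genes fell at day 1, 5 of 10 over all probe sets and 10 adjusted over the list alone (camera adjusted p = 2.08e-09, but adjusted p = 0.142 with an estimated correlation). Subunit psaD of photosystem I fell by 0.83 ± 0.14 on the log2 scale and PSBP of photosystem II fell by 0.77 ± 0.16. The 53 genes of the plastid genome were shifted downward with 1 called and 1 adjusted over the list alone (camera adjusted p = 3.38e-08, but adjusted p = 0.306 with an estimated correlation). The chalcone synthase CHS1 fell by 1.08 ± 0.17, as 1 of 5 flavonoid genes called, with 2 adjusted over the list alone (camera adjusted p = 0.0307, but adjusted p = 0.291 with an estimated correlation). Chloroplast malate dehydrogenase (chMDH) fell by 1.26 ± 0.19, and the ammonium transporter AMT1-3 fell by 1.32 ± 0.26. In all, limma called 1316 probe sets at day 1, 879 higher and 437 lower, in 686 genes higher and 316 lower. Of these probe sets 392 and 77 changed at least 2-fold. With quantile normalization limma called 795 higher and 610 lower. The count was 705 without control replicate 3, where AMT1-3 and PSBP did not pass, and 505 without Pst replicate 1, where PSBP did not pass and the lists called numbered 6 in place of 10. It was 333 in a fit of only these 6 arrays, where P4, PR1b1, PR-P2, JA3, psaD and PSBP did not pass.

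At day 3 PR genes rose in 8 of 11, and in 8 adjusted over the list alone (camera adjusted p = 7.08e-09, and adjusted p = 0.0296 with an estimated correlation). P4 was higher with Pst by 4.25 ± 0.49, TSI-1 by 3.58 ± 0.38, PR1b1 by 2.97 ± 0.23 and PR-P2 by 2.43 ± 0.22. Of 28 immune receptors and kinases 12 rose and 1 fell, with 18 and 1 adjusted over the list alone (camera adjusted p = 1.90e-08, and adjusted p = 0.0296 with an estimated correlation). Eix1, a receptor-like protein that binds fungal xylanase, rose by 1.49 ± 0.24, Ve1, known from Verticillium resistance, by 1.32 ± 0.25 and the MAP kinase MPK3 by 1.12 ± 0.18, while MAPK12 fell by 0.53 ± 0.11. WRKY factors rose in 3 of 5, and in 3 adjusted over the list alone (camera adjusted p = 0.000216, and adjusted p = 0.0296 with an estimated correlation), with WRKYIId-2 at 1.10 ± 0.14 and WRKYIId-4 at 1.04 ± 0.12. Of 6 salicylic acid genes 5 rose, and 5 adjusted over the list alone (camera adjusted p = 0.00101, but adjusted p = 0.161 with an estimated correlation), among them twi1 at 0.92 ± 0.18, NML1 at 0.57 ± 0.13 and NIM1 at 0.44 ± 0.12. NIM1 did not pass in a fit of only these 6 arrays, or without control replicate 1, 2 or 3 or Pst replicate 1 or 2.

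Jasmonate genes went both ways at day 3, with 4 higher and 3 lower of 24, and 11 and 4 adjusted over the list alone (camera adjusted p = 0.0111, but adjusted p = 0.2995 with an estimated correlation). Those higher were mcpi at 3.19 ± 0.46, ARG2 at 2.04 ± 0.40, the NAC transcription factor JA2 at 1.54 ± 0.17 and loxD at 1.43 ± 0.22. The acyl-CoA oxidase Acx1B fell by 1.58 ± 0.23, JA1 fell by 1.58 ± 0.25 and the lipoxygenase loxC fell by 0.99 ± 0.24, though it did not pass without control or Pst replicate 2. SRG1 (0.65 ± 0.19, limma adjusted p = 0.0501), JA3 (0.27 ± 0.13), PIIF (-0.04 ± 0.16) and PR-1a1 (-0.08 ± 0.12) did not pass. SRG1 lay at the threshold and passed without dim probe sets, with quantile normalization, array weights, a trended prior or only 1-gene probe sets, and without Pst replicate 2. ACO1 rose by 1.52 ± 0.15, one of 2 ethylene genes higher and 1 lower of 32, with 5 and 1 adjusted over the list alone (camera adjusted p = 0.0333, but adjusted p = 0.166 with an estimated correlation).

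Photosynthesis genes fell in 9 of 10 at day 3, and in 10 adjusted over the list alone (camera adjusted p = 2.70e-09, but adjusted p = 0.161 with an estimated correlation). The protochlorophyllide reductase POR2 fell by 1.49 ± 0.28, and the Rubisco small subunit RBCS-1 was 2.83-fold lower (limma adjusted p = 7.08e-05). Plastid genome genes fell in 15 of 53, and in 27 adjusted over the list alone (camera adjusted p = 1.64e-13, but adjusted p = 0.207 with an estimated correlation), and psbJ fell by 0.60 ± 0.12. Of 52 cell wall genes 9 fell and 2 rose, with 10 and 2 adjusted over the list alone (camera adjusted p = 0.0476, but adjusted p = 0.425 with an estimated correlation). The expansin EXP2 fell by 1.82 ± 0.36 and XET4 fell by 1.54 ± 0.20, while the pectin methylesterase PMEU1 rose by 0.92 ± 0.09. Auxin genes fell in 5 of 28 and rose in 1, with 7 and 1 adjusted over the list alone (camera adjusted p = 0.0156, but adjusted p = 0.166 with an estimated correlation), and the auxin efflux carrier PIN5 fell by 1.04 ± 0.21. Of 18 carotenoid genes 4 fell and 1 rose, with 8 and 1 adjusted over the list alone (camera adjusted p = 0.0476, but adjusted p = 0.425 with an estimated correlation). GGPS1, of geranylgeranyl diphosphate synthesis, rose by 2.97 ± 0.34, and the lycopene cyclase CrtL-e-1 fell by 1.30 ± 0.25. Outside the lists, LOC101266883 rose by 4.53 ± 0.56, LOC101249445 fell by 3.48 ± 0.41 and the myo-inositol oxygenase MIOX fell by 2.32 ± 0.49. GLK2, a transcription factor known from chloroplast development, was 3.74-fold lower (limma adjusted p = 4.98e-05). limma called 3335 probe sets, 1628 higher and 1707 lower, in 1269 genes higher and 1281 lower, and 1990 without Pst replicate 2.

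The arrays of the Pst and control groups did not overlap for 15.1% of probe sets at day 1 and 20.6% at day 3, where chance gives 10%. The responses at day 1 and day 3 share no arrays. Both had 375 genes higher and 217 lower, where independent lists give 40.8 and 18.98, and 2 genes were called in opposite directions.

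**Figure D1:**
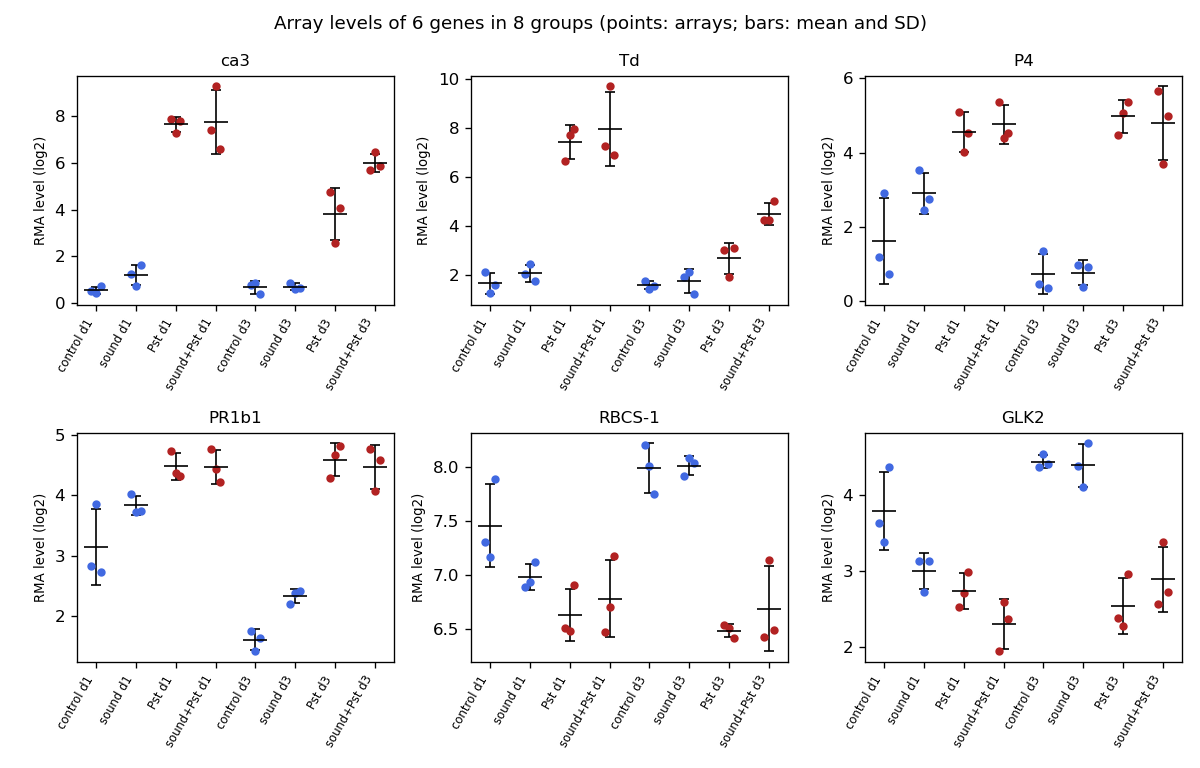
RMA levels (log2, vertical axis) of 6 genes in the 8 groups, with points for arrays (red with Pst, blue without) and bars for the mean and SD of 3 arrays. Levels of ca3 lie at 0.56 ± 0.15 (SD) in day 1 controls and 7.66 ± 0.32 with Pst, and PR1b1 lies at 3.14 ± 0.62 in day 1 controls and 1.61 ± 0.17 in day 3 controls.

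The next comparisons asked whether sound alone changed the leaves. At day 1 PR1b1 had a log2 fold change of 0.69 ± 0.23 (limma adjusted p = 0.365) and at day 3 of 0.73 ± 0.23 (limma adjusted p = 1.00), so it passed on neither day. Values of loxD were 0.47 ± 0.22 and 0.16 ± 0.22, of ACO1 0.08 ± 0.15 and 0.05 ± 0.15 and of JA3 0.08 ± 0.13 and 0.08 ± 0.13, and none passed. Of 11 PR genes 0 were called at day 1 over all probe sets and 6 were higher adjusted over the list alone (camera adjusted p = 0.106). The count of 6 rests on errors pooled over all groups. Day 1 controls varied more than day 3 controls in PR1b1, PR-P2 and TSI-1. camera called 4 lists at day 1, with 0 members called in the first, immune receptors and kinases, which were shifted upward (camera adjusted p = 0.00268, but adjusted p = 0.566 with an estimated correlation) with 2 higher adjusted over the list alone. The others were shifted downward with 0 members called even over the list alone, namely photosynthesis (camera adjusted p = 2.53e-06, but adjusted p = 0.566 with an estimated correlation), plastid genome (camera adjusted p = 8.98e-05, but adjusted p = 0.566 with an estimated correlation) and cell wall genes (camera adjusted p = 0.00789, but adjusted p = 0.566 with an estimated correlation). At day 3 camera called 0 lists.

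limma called 2 probe sets for sound at day 1, neither with a gene symbol, and they are identified here after their values were seen. Probe set 20365963 was higher by 0.95 ± 0.12 (limma adjusted p = 0.00463) and probe set 20448800 had a change of -1.32 ± 0.18 (limma adjusted p = 0.0131). At day 3 limma called 0. At an unadjusted p under 0.05 there were 6357 probe sets at day 1 and 2896 at day 3, where 3389.75 are expected by chance. Arrays did not overlap for 13.8% and 10.2% of probe sets, against 10% by chance. The day 1 count was 1 without control replicate 1, 29 without control replicate 2, 0 without sound replicate 1 or 3, 6 without sound replicate 2 and 0 in a fit of only these 6 arrays, and without control replicate 3 camera called 0 lists. The day 3 count was 1 without sound replicate 1.

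Sound was then compared on top of infection. LOC101247245 was the 1 gene called at day 1 between sound plus Pst and Pst, with a log2 fold change of -1.20 ± 0.17 (limma adjusted p = 0.0270). At day 3 the lowest p-values of named genes were those of LOC543570 (2.60 ± 0.42) and LOC101259064 (2.36 ± 0.36), which did not pass (limma adjusted p = 0.0965 for both). PIIF had changes of 0.32 ± 0.16 at day 1 and 0.56 ± 0.16 at day 3, loxD of 0.07 ± 0.22 and 0.31 ± 0.22, and PR1b1 of -0.01 ± 0.23 and -0.12 ± 0.23, and none passed. The 24 jasmonate genes were shifted upward at day 3 with 0 called and 2 higher adjusted over the list alone (camera adjusted p = 0.00166, but adjusted p = 0.410 with an estimated correlation). Polyamine and GABA genes were shifted upward at day 1 with 0 called and 0 adjusted over the list alone (camera adjusted p = 0.0146, but adjusted p = 0.813 with an estimated correlation). limma called 0 probe sets at day 3, and at an unadjusted p under 0.05 there were 3879 at day 1 and 3140 at day 3. LOC101247245 did not pass in a fit of only these 6 arrays, with the replicate number as a block, or without Pst replicate 1 or 2 or sound plus Pst replicate 1 or 3. The day 1 count was 0 without Pst replicate 1 or 2 or sound plus Pst replicate 3 and 14 without sound plus Pst replicate 2. The lists called were 0 without Pst replicate 1 or 2 or sound plus Pst replicate 2 and 3 without sound plus Pst replicate 3. The day 3 count was 3 without sound plus Pst replicate 3 and 2 with array weights, LOC543570 and LOC101259064 among them in both, and the day 3 lists called were 3 without Pst replicate 2 and 2 without any 1 of the sound plus Pst arrays.

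Whether sound altered the response to Pst was tested as an interaction. PR1b1 had an interaction of -0.70 ± 0.33 at day 1 and -0.84 ± 0.33 at day 3, loxD of -0.40 ± 0.31 and 0.15 ± 0.31, and PIIF of 0.41 ± 0.23 and 0.66 ± 0.23, and none passed. Photosynthesis genes (camera adjusted p = 0.0120, but adjusted p = 0.911 with an estimated correlation) and plastid genome genes (camera adjusted p = 0.0120, but adjusted p = 0.992 with an estimated correlation) were shifted upward in the day 1 interaction, with 0 members called in each, over all probe sets and adjusted over the list alone. At day 3 jasmonate genes (camera adjusted p = 0.00813, but adjusted p = 0.449 with an estimated correlation) and cell wall genes (camera adjusted p = 0.0195, but adjusted p = 0.449 with an estimated correlation) were shifted upward, again with 0 called in each and 0 adjusted over the list alone. Each interaction subtracts the effect of sound alone from that on top of Pst, on the same arrays. Its list shifts are therefore not separate from the shifts given for those comparisons. Without control replicate 3 camera called 0 lists for sound alone at day 1, and lists of the interactions were not tested with arrays left out. limma called 0 probe sets at day 1 and 0 at day 3, with 5920 and 2750 at an unadjusted p under 0.05. The day 1 count was 25 without sound plus Pst replicate 2, 1 without control replicate 2 or Pst replicate 1 and 1 with a trended and robust prior, and the day 3 count was 3 in a fit of that day's arrays and 3 with array weights.

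Averaged over the 4 combinations of dip and day, sound gave PR1b1 a change of 0.32 ± 0.12 (limma adjusted p = 0.728) and loxD one of 0.25 ± 0.11, and neither passed. Photosynthesis genes were shifted downward in this average with 0 called and 0 adjusted over the list alone (camera adjusted p = 0.000111, but adjusted p = 0.587 with an estimated correlation). The effect of sound was also compared between the days. Immune receptors and kinases had a lower effect at day 3 (camera adjusted p = 0.0195, but adjusted p = 0.867 with an estimated correlation), and photosynthesis (camera adjusted p = 0.0195, but adjusted p = 0.867 with an estimated correlation) and plastid genome genes (camera adjusted p = 0.00874, but adjusted p = 0.867 with an estimated correlation) a higher one, with 0 members called and 0 adjusted over the list alone in each. The average and the difference of days both contain sound against control at day 1, so their list shifts are not separate from those there. Lists were not tested with arrays left out in either. limma called 0 probe sets for the average and 0 for the difference of days, with 4082 and 4048 at an unadjusted p under 0.05. The average gave 1 without sound day 3 replicate 3, and the difference of days 2 without sound day 1 replicate 2.

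Plants exposed to the sound were compared with and without Pst. At day 1 ca3 rose by 6.56 ± 0.48, Td by 5.89 ± 0.50, mcpi by 4.70 ± 0.46, lap2 by 3.75 ± 0.34 and loxD by 1.82 ± 0.22. Of 24 jasmonate genes 14 rose and 2 fell, with 15 and 4 adjusted over the list alone (camera adjusted p = 4.51e-11, and adjusted p = 0.0291 with an estimated correlation). Polyamine and GABA genes rose in 5 of 13, with 8 higher and 1 lower adjusted over the list alone (camera adjusted p = 1.49e-06, and adjusted p = 0.0293 with an estimated correlation). At day 3 P4 rose by 4.02 ± 0.49, PR1b1 by 2.13 ± 0.23, Ve1 by 1.70 ± 0.25 and Eix1 by 1.67 ± 0.24, while RBCS-1 fell by 1.32 ± 0.20 and PsbQ of photosystem II fell by 1.33 ± 0.24. PR genes rose in 9 of 11, and 9 adjusted over the list alone (camera adjusted p = 2.30e-10, and adjusted p = 0.0248 with an estimated correlation). Immune receptors and kinases rose in 11 of 28, with 15 higher and 1 lower adjusted over the list alone (camera adjusted p = 2.14e-08, and adjusted p = 0.0248 with an estimated correlation).

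In these plants limma called 649 genes higher and 1118 lower with Pst at day 1, and 1111 and 870 at day 3. This comparison shares no arrays with Pst against control. At day 1 402 genes were higher and 170 lower in both, where independent lists give 20.9 and 16.6. At day 3 the numbers were 843 and 669, where independent lists give 66.1 and 52.3, and 0 genes went in opposite directions on either day. Across 11840 genes with a mean level over 3, which are not independent replicates, the fold changes correlated at 0.813 at day 1 and 0.908 at day 3. The 2402 probe sets called at day 1, 872 higher and 1530 lower, were 1186 without sound replicate 1, 864 without sound replicate 2, 1063 without sound plus Pst replicate 1 and 512 in a fit of only these 6 arrays. With quantile normalization limma called 2041 probe sets, 932 higher and 1109 lower. The 2554 at day 3, 1404 higher and 1150 lower, were 1650 and 1630 without sound replicate 2 or 3, and 1426 and 1359 without sound plus Pst replicate 1 or 3. With quantile normalization 2717 were called, 1309 higher and 1408 lower.

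Against mock-dipped controls in silence, leaves with sound plus Pst had ca3 higher by 7.20 ± 0.48, Td by 6.30 ± 0.50, P4 by 3.15 ± 0.49 and adc1 by 1.59 ± 0.17 at day 1, while AMT1-3 fell by 1.99 ± 0.26 and the ethylene response factor ERF4 fell by 1.26 ± 0.16. At day 3 ca3 rose by 5.33 ± 0.48, P4 by 4.07 ± 0.49, PR1b1 by 2.86 ± 0.23 and mcpi by 4.01 ± 0.46, and PsbQ fell by 1.42 ± 0.24. Jasmonate genes rose in 14 of 24 at day 1 and fell in 2, with 16 and 4 adjusted over the list alone (camera adjusted p = 7.07e-10, and adjusted p = 0.0456 with an estimated correlation). PR genes rose in 9 of 11 at day 3, and 9 adjusted over the list alone (camera adjusted p = 3.77e-09, and adjusted p = 0.0326 with an estimated correlation). In all 1061 genes were higher and 917 lower at day 1, and 1240 and 961 at day 3. Over probe sets there were 1358 higher and 1238 lower at day 1 and 1577 and 1292 at day 3. With quantile normalization more were lower than higher, 1284 higher and 1456 lower at day 1 and 1479 and 1508 at day 3. This comparison shares its control arrays with Pst against control. At day 1 723 probe sets were higher and 350 lower in both, where independent lists give 17.6 and 7.98. At day 3 the numbers were 1197 and 1032, where independent lists give 37.9 and 32.5. Simulated unchanged groups give an overlap of 0 on either day. Unchanged groups yield hardly any calls, so this 0 cannot tell how much overlap the shared controls make. The covariance of the fold changes was 0.182 at day 1 and 0.233 at day 3, and 0.0153 in simulated unchanged groups on either day (20 simulations), and part of the excess may come from the shared controls. The 2596 probe sets at day 1 were 1438 without control replicate 3, 1286 without sound plus Pst replicate 1 and 337 in a fit of only these 6 arrays, and the 2869 at day 3 were 1759 and 1620 without sound plus Pst replicate 1 or 3.

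**Figure D2:**
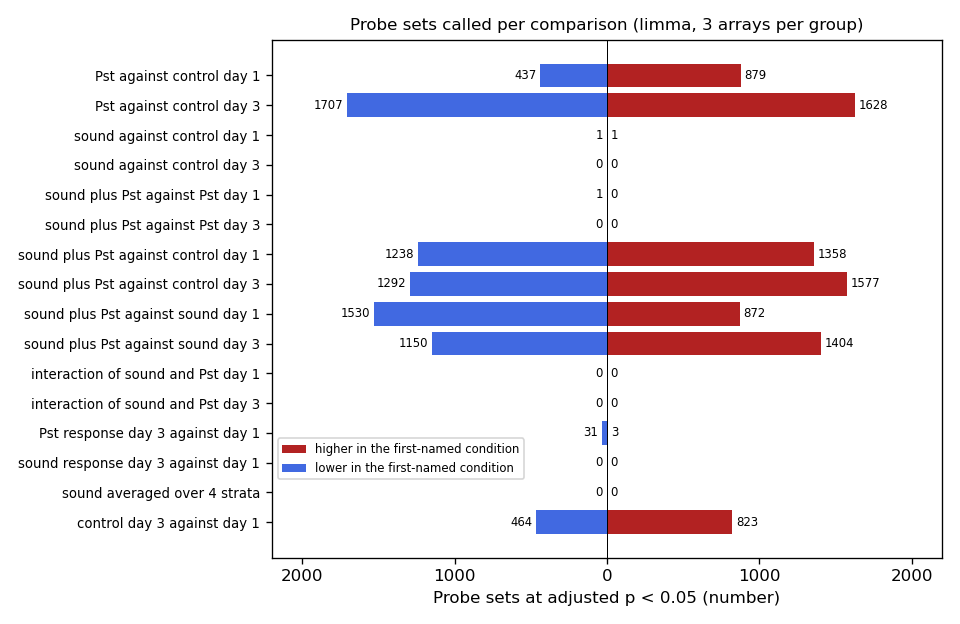
Number of probe sets with a limma adjusted p under 0.05 (horizontal axis) in each of 16 comparisons, higher to the right in red and lower to the left in blue. Pst against control at day 3 has 1628 higher and 1707 lower, and the comparisons of sound with silence have 0 to 2 in all.

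The response to Pst was compared between the days. Td had a lower response at day 3 by a log2 difference of -4.69 ± 0.71, ca3 of -3.97 ± 0.68, MIOX of -3.82 ± 0.70, lap2 of -2.64 ± 0.48, GAME1, of glycoalkaloid synthesis, of -2.18 ± 0.40 and SPM1 of -1.21 ± 0.23, while LOC101260685 had a higher one (1.85 ± 0.24). The level of LOC101260685 was 5.26 ± 0.11 (SD) in controls and 4.42 ± 0.11 with Pst at day 1, and 3.44 ± 0.12 and 4.46 ± 0.35 at day 3. PR1b1 (1.64 ± 0.33, limma adjusted p = 0.0711) and loxD (-0.79 ± 0.31) did not pass. Jasmonate genes had a lower response at day 3, with 2 of 24 called and 6 adjusted over the list alone (camera adjusted p = 2.07e-05, but adjusted p = 0.138 with an estimated correlation). PR genes (camera adjusted p = 0.000125, but adjusted p = 0.150 with an estimated correlation) and immune receptors and kinases (camera adjusted p = 2.07e-05, but adjusted p = 0.138 with an estimated correlation) had a higher one with 0 called in each, and 2 and 5 higher and 0 and 1 lower adjusted over the list alone. The mean response of immune receptors and kinases was 0.18 at day 1 and 0.46 at day 3, and their mean change in controls between the days was -0.20. For PR genes these means were 0.98, 1.67 and -0.66. By these means, the fall in the controls made up nearly all of the higher response of PR genes. It made up most of that of immune receptors and kinases. The higher PR response therefore does not show that PR genes rose in leaves with Pst between the days. Among the PR genes, PR1b1 had a level of 3.14 ± 0.62 in controls and 4.48 ± 0.23 with Pst at day 1, and 1.61 ± 0.17 and 4.58 ± 0.27 at day 3. For PR-P2 these were 3.30 ± 0.63, 4.91 ± 0.30, 2.38 ± 0.22 and 4.81 ± 0.02, and for TSI-1 2.67 ± 1.09, 5.61 ± 0.61, 1.36 ± 0.27 and 4.94 ± 0.43. Trichome and terpene genes (camera adjusted p = 0.0285, but adjusted p = 0.138 with an estimated correlation) and plastid genome genes (camera adjusted p = 0.00256, but adjusted p = 0.732 with an estimated correlation) had a lower one, with 0 called in each and 2 and 0 lower adjusted over the list alone. limma called 34 probe sets, 3 with a higher and 31 with a lower response at day 3. Other settings gave 19 in a fit of only these groups, 79 with only 1-gene probe sets and 7 with the replicate number as a block. The count was 17 and 190 without control replicate 2 or 3 of day 1, 4 and 5 without Pst replicate 2 or 3 of day 1, 18, 18 and 7 without control replicate 1, 2 or 3 of day 3, and 57, 8 and 10 without Pst replicate 1, 2 or 3 of day 3. PR1b1 passed without control replicate 3 of day 1 or Pst replicate 1 of day 3 and with only 1-gene probe sets. The calls of LOC101260685 and LOC101263597 (-3.83 ± 0.54) held in every setting run. Those of Td, LOC101265368 (-5.04 ± 0.92), ca3, MIOX, lap2, GAME1 and SPM1 ended without Pst replicate 2 or 3 of day 1 or Pst replicate 2 of day 3, and all of these but Td also without control replicate 1 or 2 of day 1 or replicate 3 of either group of day 3. Calls that also ended were those of ca3, MIOX, lap2 and SPM1 without Pst replicate 1 of day 1, of these and LOC101265368 without control replicate 2 of day 3, of LOC101265368, ca3, lap2, GAME1 and SPM1 without control replicate 1 of day 3, and of lap2 and SPM1 without Pst replicate 1 of day 3. With a trended and robust prior LOC101265368, ca3, MIOX, lap2 and GAME1 did not pass, nor did MIOX, GAME1 and SPM1 in a fit of only these groups. The replicate block ended the calls of LOC101265368, ca3, MIOX, lap2, GAME1 and SPM1.

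Control leaves, with neither sound nor Pst, were compared between the days. Flavonoid genes rose in 4 of 5 by day 3, and 4 adjusted over the list alone (camera adjusted p = 1.59e-05, but adjusted p = 0.106 with an estimated correlation), with CHS2 at 1.27 ± 0.15 and CHS1 at 1.15 ± 0.17. The chlorophyll-binding protein CAB4 rose by 1.74 ± 0.21 and AMT1-3 by 1.45 ± 0.26, and 1 of 10 photosynthesis genes was called, with 7 higher adjusted over the list alone (camera adjusted p = 4.41e-05, but adjusted p = 0.371 with an estimated correlation). Of 18 carotenoid genes 4 rose and 1 fell, with 8 and 1 adjusted over the list alone (camera adjusted p = 0.000308, but adjusted p = 0.341 with an estimated correlation). PR genes fell in 2 of 11, and in 6 adjusted over the list alone (camera adjusted p = 4.41e-05, but adjusted p = 0.130 with an estimated correlation), with PR1b1 at -1.53 ± 0.23. Immune receptors and kinases were shifted downward with 0 called and 5 lower adjusted over the list alone (camera adjusted p = 0.000141, but adjusted p = 0.130 with an estimated correlation). Cell wall genes were shifted downward too, with 1 higher and 2 lower, and 3 and 5 adjusted over the list alone (camera adjusted p = 0.0269, but adjusted p = 0.511 with an estimated correlation). The ribonuclease gene rnale fell by 2.68 ± 0.49 and AADC1A, an aromatic amino acid decarboxylase, fell by 1.21 ± 0.22. CO1, of the CONSTANS type and the only measured member of the circadian clock list, rose by 2.07 ± 0.29. limma called 1287 probe sets, 823 higher and 464 lower at day 3, in 550 genes higher and 316 lower (with quantile normalization 679 probe sets higher and 535 lower), and the arrays of the days did not overlap for 17.2% of probe sets (chance gives 10%). The count was 809 and 623 without replicate 1 or 2 of day 1, 841, 585 and 590 without replicate 1, 2 or 3 of day 3, and 304 in a fit of only these 6 arrays, where PR1b1 did not pass.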

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

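The tests of single arrays, of the control change gene by gene, of the size of the changes in sound plants and of the arrays exchanged by the splits in this part were chosen after the result was seen.

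The response to Pst differed between day 3 and day 1 for 34 probe sets, by a limma test of the difference itself over all probe sets. Calls numbered 7 with the replicate number as a block, 19 in a fit of only these groups and 79 with only 1-gene probe sets. The named genes with a lower response at day 3 were LOC101265368 (-5.04 ± 0.92, log2, SE, n = 3 per group), Td (-4.69 ± 0.71), ca3 (-3.97 ± 0.68), LOC101263597 (-3.83 ± 0.54), MIOX (-3.82 ± 0.70), lap2 (-2.64 ± 0.48), GAME1 (-2.18 ± 0.40) and SPM1 (-1.21 ± 0.23), and LOC101260685 (1.85 ± 0.24) had a higher one.

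One technical explanation is that a single array decides these calls, and the lowest count with 1 array left out was 4, without Pst day 1 replicate 2, which is in line with it, while the count was 190 without control day 1 replicate 3, and the calls of LOC101260685 and LOC101263597 held with each array left out, which argues against a single array for those genes. Another is a change in the controls between the days, for which the median share of the change that lay in the controls, 0.368, hides genes that differ, since of 26 called genes 6 had a share under 0.25 and 8 over 0.5 by more than the error. The share was -0.0150 for Td, 0.0287 for ca3, 0.0387 for LOC101265368, -0.0969 for LOC101263597 and -0.258 for lap2, which argues against the controls for these genes, and 0.981 for LOC101260685, in line with them, where controls went from 5.26 ± 0.11 (SD) to 3.44 ± 0.12 and leaves with Pst from 4.42 ± 0.11 to 4.46 ± 0.35. For MIOX (0.269), SPM1 (0.320) and GAME1 (0.456) the share passed neither bound by more than the error, so the bounds do not decide. In these genes, in that order, leaves with Pst changed by -2.80, -0.823 and -1.19 between the days. Controls changed by 1.03 ± 0.49, 0.387 ± 0.160 and 0.996 ± 0.281 (SE), so both may have had a part. A time course of the response to Pst needs the same signs in sound plants, other arrays, and 100% of the called genes had them (21 by over 2 SE, 4 called there too, 3 changed by less than 0.1), but a control change shared by sound plants would give them too, except for the 6 genes with a share under 0.25, 5 of which had them by over 2 SE.

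Of 100 splits of the arrays between the days, 7 gave at least as many calls as the real 34, so chance is not excluded for the count. The highest other split gave 175, several times the real count. That split left the control arrays in their days and exchanged 2 Pst arrays of each day. Each of the others with at least as many calls left either the controls or the Pst arrays in place, so the difference between the days, itself a structure of the samples, was part of them. Whether anything else raised those counts was not tested. The count was 17 and 190 without control day 1 replicate 2 or 3, 4 and 5 without Pst day 1 replicate 2 or 3, 18, 18 and 7 without control day 3 replicate 1, 2 or 3, and 57, 8 and 10 without Pst day 3 replicate 1, 2 or 3. Within a group, 3 arrays are too few for a test of single arrays far from the others. Array weights, estimated over all groups, gave a count of 40.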

How the results depend on the processing

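No alternative was chosen after the results were seen. Of 62 named genes called for Pst at day 1, 33 lost the call in some setting and 22 with some array left out. Of 80 at day 3, 14 and 22 did, and 0 named genes changed direction on either day. In a fit of only the groups compared, which estimates the spread from fewer arrays, the calls were 333 for Pst at day 1, 0 for sound at day 1, 0 for sound plus Pst against Pst at day 1, 337 against control at day 1, 512 against sound at day 1, 3 for the interaction at day 3, 19 for the response to Pst between days and 304 for controls between days. For the average of sound this fit has all groups and was not run. At day 3, with as few arrays, this fit gave 3229 for Pst, 2696 for sound plus Pst against control and 2147 against sound. The main counts there were 3335, 2869 and 2554. Fewer arrays alone therefore do not explain the lower counts of the responses to Pst at day 1. Control arrays of day 1 correlated less with their own group than those of day 3, but the cause was not tested. Same-numbered arrays deviated together at a mean correlation of 0.0572 at day 1 and -0.0192 at day 3, with 7 and 0 of 18 pairs over 0.1. Differently numbered arrays had means of -0.0287 and 0.00973, with 6 and 3 of 36 pairs over it, and 7 of 24 arrays were closest to their own number. Deviations within a group sum to 0, so these means largely follow from those of same-numbered arrays and are no separate comparison. Day 1 leaned toward pairing, but the rule that every pair lie over 0.1 was not met, so the samples were taken to share only a number. The replicate block gave 0 calls for sound plus Pst against Pst at day 1, where LOC101247245 did not pass, and 7 for the response to Pst between days, where LOC101265368, ca3, MIOX, lap2, GAME1 and SPM1 did not pass, and moved no other count by over 1.5 times. A trended and robust prior gave 1 for the interaction at day 1, and array weights 2 for sound plus Pst against Pst at day 3 and 3 for the interaction at day 3. With only probe sets of 1 gene, sound at day 1 gave 0, because both probe sets called there have no gene and are left out, and the response to Pst between days, with fewer tested, gave 79. The block also let SRG1 pass for Pst at day 3. The dim filter and quantile normalization moved no count by over 1.5 times. With an estimated correlation 1 of 10 lists stayed called for Pst at day 1, 3 of 11 at day 3, 0 of 4 for sound at day 1 and 0 for sound plus Pst against Pst on either day. fry, which does not compare a list with other genes, called 17 for Pst at day 1, 1 for sound at day 1 and 0 for sound plus Pst against Pst on either day. The 1 for sound was immune receptors and kinases, shifted upward (fry adjusted p = 0.0191). fry was not run with arrays left out. Where no reason is given, the cause was not tested. With 1 array left out, the group keeps 2 arrays and the fit pools the spread of all groups. Calls then ranged from 505 to 1597 for Pst at day 1, 1990 to 2836 at day 3, 0 to 29 for sound at day 1, 0 to 1 at day 3, 0 to 14 and 0 to 3 for sound plus Pst against Pst, 1286 to 2832 and 1620 to 2622 against control, 864 to 3475 and 1359 to 2403 against sound, 0 to 25 and 0 to 0 for the interactions, 4 to 190 and 0 to 2 for the responses to Pst and to sound between days, 0 to 1 for the average of sound and 585 to 1787 for controls between days. Lists called ranged from 6 to 10 and 8 to 11 for Pst, 0 to 6 and 0 to 0 for sound, and 0 to 3 and 1 to 3 for sound plus Pst against Pst. Signal over background is unknown, so no gene can be called absent.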

Other observations

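In this part the tests of the score, of single control arrays and of defence genes fading in controls were chosen after the results were seen.

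The other gene lists were tested for the response to Pst as well. At day 1 salicylic acid genes had 0 higher and 0 lower of 6 (3 and 0 adjusted over the list alone, camera adjusted p = 0.0164, but adjusted p = 0.291 with an estimated correlation). Immune receptors and kinases had 1 higher and 0 lower of 28 (8 and 1 adjusted over the list alone, camera adjusted p = 0.0369, but adjusted p = 0.306 with an estimated correlation). Abscisic acid and drought genes had 1 higher and 0 lower of 18 (2 and 0 adjusted over the list alone, camera adjusted p = 0.0495, but adjusted p = 0.291 with an estimated correlation). camera called none of the following lists at day 1, and its lowest adjusted p among them was 0.0878, for calcium and touch genes. Ethylene genes had 4 higher and 1 lower of 32 (4 and 1 adjusted over the list alone), and phenylpropanoid genes 1 higher and 0 lower of 6 (1 and 0 adjusted over the list alone). Oxidative stress genes had 2 higher and 1 lower of 20 (3 and 2 adjusted over the list alone), and calcium and touch genes 1 higher and 0 lower of 14 (3 and 0 adjusted over the list alone). Cytokinin genes had 2 higher and 0 lower of 14 (3 and 2 adjusted over the list alone), and gibberellin and brassinosteroid genes 1 higher and 0 lower of 21 (1 and 0 adjusted over the list alone). Cell wall genes had 1 higher and 0 lower of 52 (1 and 1 adjusted over the list alone), and trichome and terpene genes 1 higher and 0 lower of 7 (2 and 0 adjusted over the list alone). Carotenoid genes had 1 higher and 2 lower of 18 (1 and 2 adjusted over the list alone), and sucrose and sugar genes 1 higher and 1 lower of 18 (2 and 1 adjusted over the list alone). Over all probe sets limma called 0 of the heat shock (14 genes), auxin (28), reproductive organ (13), cell cycle (18), ribosome and translation (9) and senescence genes (6). Adjusted over the list alone, 2 senescence genes were higher, 1 cell cycle and 1 ribosome and translation gene were lower, and 0 passed in the other lists. The mean change was above 0 and the camera direction downward for gibberellin and brassinosteroid (mean 0.05), cell cycle (0.02) and carotenoid genes (0.04).

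At day 3 the cell wall invertase Wiv-1 rose by 1.83 ± 0.21 and the hexose transporter ht1 by 0.92 ± 0.15, among sucrose and sugar genes with 3 higher and 0 lower of 18 (3 and 1 adjusted over the list alone, camera adjusted p = 0.245). The catalase CAT2 fell by 1.12 ± 0.20 and DHAR2, of ascorbate recycling, fell by 0.91 ± 0.11, among oxidative stress genes with 4 higher and 2 lower of 20 (7 and 2 adjusted over the list alone, camera adjusted p = 0.426). SlCKX4 rose by 1.74 ± 0.17, among cytokinin genes with 2 higher and 2 lower of 14 (2 and 2 adjusted over the list alone, camera adjusted p = 0.515). The phosphatase PP2C-2 rose by 1.29 ± 0.22, among abscisic acid and drought genes with 2 higher and 0 lower of 18 (3 and 2 adjusted over the list alone, camera adjusted p = 0.205), and SGR1, known from chlorophyll breakdown, by 0.96 ± 0.17, among senescence genes with 1 higher and 0 lower of 6 (2 and 1 adjusted over the list alone, camera adjusted p = 0.245). Polyamine and GABA genes had 4 higher and 1 lower of 13 (6 and 1 adjusted over the list alone, camera adjusted p = 0.205), with adc1 higher by 1.27 ± 0.17. Calcium and touch genes had 2 higher and 0 lower of 14 (2 and 0 adjusted over the list alone, camera adjusted p = 0.364). Phenylpropanoid genes had 1 higher and 0 lower of 6 (2 and 0 adjusted over the list alone, camera adjusted p = 0.0592). Flavonoid genes had 0 higher and 1 lower of 5 (0 and 2 adjusted over the list alone, camera adjusted p = 0.205). Gibberellin and brassinosteroid genes had 1 higher and 1 lower of 21 (1 and 1 adjusted over the list alone, camera adjusted p = 0.938). Trichome and terpene genes had 0 higher and 1 lower of 7 (0 and 1 adjusted over the list alone, camera adjusted p = 0.278). Heat shock genes had 0 higher and 0 lower of 14 (0 and 0 adjusted over the list alone, camera adjusted p = 0.835). Cell cycle genes had 0 higher and 0 lower of 18 (0 and 0 adjusted over the list alone, camera adjusted p = 0.850). Ribosome and translation genes had 0 higher and 1 lower of 9 (0 and 1 adjusted over the list alone, camera adjusted p = 0.853). Genes of reproductive organs had 0 higher and 0 lower of 13 (0 and 0 adjusted over the list alone, camera adjusted p = 0.850). For ribosome and translation genes the median change was 0.02 and the camera direction downward. Of the lists too short to test, the vascular genes SUT1, SUT2 and SUT4 had changes of 0.10 ± 0.11, 0.38 ± 0.14 and 0.49 ± 0.21 with Pst at day 1 and 0.46 ± 0.11, 0.28 ± 0.14 and 0.46 ± 0.21 at day 3, where SUT1 passed, but not in a fit of only these 6 arrays or without control replicate 2 or 3 or Pst replicate 2 (SUT2 passed at day 1 without control replicate 2), and the circadian gene CO1 had -0.61 ± 0.29 at day 3 and did not pass.

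Control leaves differed between the days at 1287 probe sets. Of the 866 genes called, 98.3% changed the same way in sound plants, which share no array with the controls, and 608 were called there too, in line with a change shared by mock-dipped plants. The 649 genes called higher with Pst among sound plants at day 1 had a median change in controls of -0.19 and 69.8% of them fell, while the 1118 called lower had a median of 0.21, so defence genes active at day 1 after the dip or handling may have faded by day 3. The lowest count with 1 control array left out was 585, without day 3 replicate 2 (others were 809 and 623 without day 1 replicate 1 or 2, and 841 and 590 without day 3 replicate 1 or 3), which argues against a single array as the whole cause. Age, handling and time since the dip were not separated.

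Leaves with sound at day 1 lay toward the response to Pst on a score, the mean level of 1269 genes called higher with Pst at day 3 minus that of 1281 called lower, by 0.335 ± 0.247 (SE, n = 3 per group, two-sided exact permutation p = 0.4). Without control replicate 1, 2 or 3 it was 0.322, 0.553 and 0.131, and the share of 0.391 kept without control replicate 3 is in line with that 1 array setting most of the lean. If sound raised the score, the 3 other strata should lie above 0 by over 2 standard errors, and 1 did: with genes from day 1 (686 higher and 316 lower) the differences were 0.115 ± 0.0351 for sound at day 3 and 0.171 ± 0.115 for sound on top of Pst at day 3, and with genes from day 3 0.173 ± 0.187 on top of Pst at day 1. Their two-sided exact permutation p-values were 0.1, 0.3 and 0.5, where 0.1 is the smallest possible, and at day 3 the sound arrays (-1.55, -1.57 and -1.65) all scored above the controls (-1.70, -1.73 and -1.68), so an effect of sound on the score stays open. The score was redefined after a first form, which took genes from day 3 for all arrays, had been seen, and the stratum of sound on top of Pst at day 3 changed sign with this.

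The 6 arrays of a comparison can be split in 10 ways, too few for a share under 0.05. The real count and the highest of the other splits were 1316 and 0 for Pst at day 1, 3335 and 1 at day 3, 2 and 1 for sound at day 1, and 0 and 3 at day 3. For sound plus Pst they were 2596 and 88 against control at day 1, 2869 and 0 at day 3, 2402 and 0 against sound at day 1, 2554 and 0 at day 3, and 0 and 0 against Pst at day 3. For controls between days they were 1287 and 33. In sound plus Pst against Pst at day 1 the real count was 1 and 7 of the splits gave as many. The highest other gave 21, for a reason that was not looked into. Of 100 splits drawn for the comparisons of more than 6 arrays, 100 gave at least the 0 calls of either interaction, of sound between days and of the average of sound, as any split must, so these splits say nothing about chance. The highest others were 62 for the day 1 interaction, again for a reason that was not looked into, 1 for day 3, 3 for sound between days and 5 for the average.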
